A study of Mus musculus with 6 samples.

How the data were processed

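RNA of RAW264.7 mouse macrophages was sequenced from 6 libraries, 3 of sorted cells grown alone and 3 of sorted cells cocultured for 48 h with Tsc2-null TTJ cells. Per the labels' protocols, total RNA was selected with poly-T beads, fragmented and reverse transcribed with random hexamers, and paired reads were taken on a NovaSeq X Plus. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0, edgeR 3.22.5 and the build mm10, without the role of each. The strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes could not be told apart, and near-identical paralogs and pseudogenes may share or lose reads.

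The authors deposited a table of raw counts per gene for 54532 genes with gene names, biotypes and coordinates, per the file headers, and a table of FPKM values of the same 6 libraries. Checked against the counts, each deposited FPKM value equalled the count divided by gene length and library total, times a factor per library between 0.996 and 1.00. No row was blank or a total (0 rows), and 0 columns belonged to other samples. Of the gene IDs, 54409 were in GENCODE M21 (GRCm38, the assembly of mm10), and 53499 of these (98.3%) had the same coordinates. Gene names were taken from the deposited table, and older symbols on the lists were matched to current ones. There were 102 symbols on more than 1 gene ID.

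Total counts ran from 14329487 to 17358280 per library. Replicates were compared before they were averaged. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.10 to 4.82 over genes and Pearson's r of log2 CPM across genes of 0.992 to 0.994. Genes are not independent replicates, and these r values describe the libraries only. The common biological coefficient of variation was 5.29%. A group whose libraries were all at 0 was set to 3 counts over the group for lower bounds of folds. Genes with 1 to 3 counts alone were given a ratio with an exact conditional binomial 95% interval. Bounds and intervals cover counting error only.

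The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, filterByExpr by group (12972 genes kept) and a single group term. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and SE is the absolute log2 fold change over the square root of F. CPM values use TMM-scaled library sizes. The 25 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a correlation preset at 0.01, adjusted over the 25 lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry asks whether its genes move one way on balance. A gene counts as measured where it passed the filter. A gene with no count alone can pass the filter only through the cocultured libraries, so its direction is fixed and its rise is no independent support for its list.

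The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Mrc1, Arg1, Nos2, Tnf, Il1b, Tsc2 and Adgre1. It added the 6 protein-coding genes with the largest rise and the 6 with the largest fall among those past the threshold with at least 5 CPM in the higher group and no overlap of the groups. From each list it took up to 3 members past the threshold with the largest change and at least 1 CPM in the higher group, or, with none, up to 2 of the highest mean CPM. Some genes that the rule took are not reported here. Further list members that were too low to test are named with their counts. Klf4, Egr2, Cxcl2 and Cx3cr1, which fell on lists called higher, are also named, as are Clec10a, Clec7a, Pparg and Irf4. All of these were chosen after their values were seen.

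The alternatives were DESeq2 size factors and upper quartile scaling in the same edgeR fit, no filter, at least 1 CPM in at least 3 libraries, protein-coding genes, genes with at least 1 CPM in lone cells, the replicate letter as a block, each library left out in turn, the DESeq2 1.42.0 Wald test, limma-voom, and limma with a trend on log2(FPKM + 1), on log2(FPKM + 0.1) and on genes with a mean FPKM of at least 1. A limit of at least 10 CPM in lone cells was added after seeing the data. Fold changes on the FPKM scale understate changes of low genes because of the pseudocount. Lists without members shared with other lists were also tested.

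The procedure was tested on simulated data before use, for coculture against alone. Counts were drawn independently for each gene, from the means of the lone libraries and the depths of all libraries, and 12022 genes passed the filter. It recovered 77.6% of 67 genes changed by a log2 of 0.5, 83.6% of 67 changed by 1 and 100% of 66 changed by 2. Of its calls, 4.40% were unchanged genes (8 calls). It called the changed list and 0 of 24 unchanged lists. Because genes were drawn independently, the simulation cannot show false list calls that correlation between genes would cause. Far fewer genes were changed in it than were called in the real data, so its false share may not hold there. Figures were drawn with matplotlib 3.10.9. No library of TTJ cells was used here.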

Results

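The study measured messenger RNA in RAW264.7 cells, a mouse macrophage line, that had been collected by fluorescence-activated sorting after growth alone or after 48 h of coculture with TTJ cells. TTJ cells lack Tsc2, a brake on mTORC1 signalling, and were established from an angiomyolipoma, a mixed tumour of vessels, muscle and fat, of mice that model tuberous sclerosis complex. Each group had 3 libraries, named replicates A, B and C. The total counts were 14621832, 16700748 and 17358280 for RAW264.7 cells alone and 14329487, 15643602 and 16976782 for cocultured RAW264.7 cells. At this depth 3 counts over a whole group, the limit that a count of 0 allows, corresponded to 0.0618 CPM (counts scaled to library size) alone and 0.0639 CPM in coculture. Values below are mean CPM ± SD with n = 3 per group, and coordinates are on mm10. No label says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The mitochondrial share of counts was 1.65% ± 0.0995 alone and 1.39% ± 0.0377 in coculture, without overlap between the groups. An exact two-sided permutation test of 3 against 3 cannot go below p = 0.1, so that share was not tested.

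The comparison of cocultured with lone RAW264.7 cells asks how Tsc2-null cells alter macrophage polarization, and the title of the series names CD206, the mannose receptor encoded by Mrc1, and the lung disease lymphangioleiomyomatosis. The cocultured libraries held renal and epithelial transcripts that lone RAW264.7 cells lacked, higher interferon response, antigen presentation, chemokine and efferocytosis genes, and lower immediate early and oxidative phosphorylation genes, list changes that passed with a preset correlation between genes, whereas 0 of 16 such lists passed with an estimated one. Of 12972 genes tested, 2819 were higher and 1974 lower in coculture. Changes of at least 2-fold were found for 1212 genes that rose and 58 that fell. Among genes with at least 1 CPM in lone cells, fitted on their own, 332 rose and 47 fell at least 2-fold. Among genes with at least 10 CPM in lone cells, a limit chosen after seeing the data, 89 rose and 13 fell at least 2-fold. The first principal component held 91.6% of the variance of log2 CPM and separated the groups. Tests were edgeR quasi-likelihood tests with Benjamini-Hochberg adjusted p under 0.05.

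**Figure D1:**
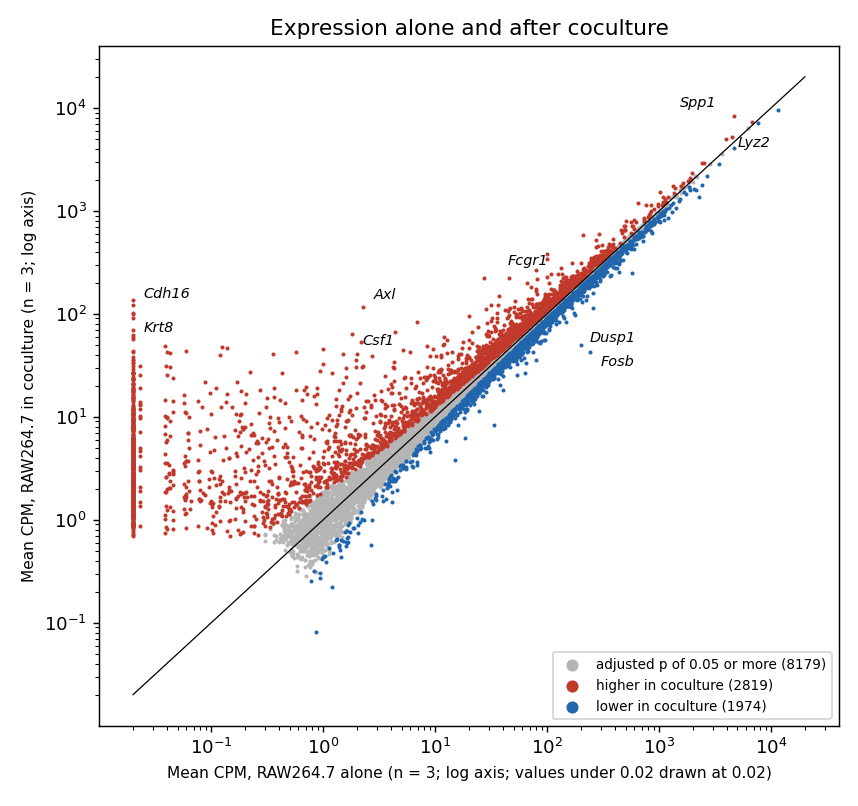
Mean CPM of each of the 12972 genes tested, in RAW264.7 cells alone (x axis, log scale, values under 0.02 drawn at 0.02) and in coculture (y axis, log scale), with 3 libraries per group. The 2819 red genes rose and the 1974 blue genes fell, and the column of red points at the left edge holds genes with no or almost no counts alone, among them Cdh16 and Krt8.

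Markers of another cell type were present in the cocultured libraries. Of the 15 genes of the renal and simple epithelial list, 11 were measured and all 11 rose, 8 of them from 0 counts in all 3 lone libraries. Cdh16, the kidney-specific cadherin (chromosome 8, 104601911 to 104624396), went from 0 to 122 ± 12.2 CPM and was at least 1987-fold higher, with the lower bound set by 3 counts over the lone group. Krt8, a keratin of simple epithelia, reached 91.8 ± 8.36 CPM (at least 1488-fold higher), and Cdh1, which encodes E-cadherin, reached 43.2 ± 2.27 CPM (at least 697-fold higher). The median log2 change of the list was 10.98 as fitted and 9.05 with genes absent alone at their bound and those with 1 to 3 counts at their ratio (camera adjusted p = 1.66e-14; adjusted p = 0.0768 with an estimated correlation). None of the 11 reached 1 CPM in lone cells, and their CPM alone summed to 0.0813. They passed the filter only through the cocultured libraries, so their direction was fixed and the camera p says little. The other 4 members were too low to test, with 3 counts for Krt19 and 0 for Epcam, Cldn7 and Lhx1 over the cocultured libraries. Further genes with the largest rises were also at 0 counts alone. Nedd4, a ubiquitin ligase, reached 102 ± 9.40 CPM (at least 1654-fold higher), Itga3, an integrin chain, 99.9 ± 10.0 CPM (at least 1618-fold) and Prl2c2, a member of the proliferin family, 62.3 ± 4.87 CPM (at least 1014-fold). Reads of Prl2c2 are uncertain because near-identical family members exist.

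The mesenchymal and smooth muscle list gave 10 rises among 11 measured members, while 21 of its 32 genes were too low to test. Timp3, a metalloprotease inhibitor, went from 0 to 17.9 ± 2.45 CPM (at least 291-fold higher). Col5a1, a fibrillar collagen chain, had 1 count alone and 25.6 ± 0.126 CPM in coculture, a ratio of 1244 with an exact 95% interval of 223 to 49183 that covers counting error only. Cav1, the caveolae protein, had 1 count alone and 15.2 ± 0.566 CPM in coculture, a ratio of 736 (132 to 29126). Timp3, Col5a1 and Cav1 passed the filter only through the cocultured libraries, so their direction was fixed. The fitted log2 change of Col5a1 was 9.81 and became 11.70 without alone replicate A, and that of Cav1 went from 9.06 to 10.89 without alone replicate C. Col1a1 had 3 counts and Col3a1 had 0 counts over the 3 cocultured libraries. The list median was 8.71 as fitted and 8.19 with genes absent alone at their bound and genes with 1 to 3 counts alone at their ratio (camera adjusted p = 1.08e-09; adjusted p = 0.0599 with an estimated correlation), and 1 of the 11 members reached 1 CPM in lone cells. Of the 9 melanocytic and lymphangioleiomyomatosis genes 2 were measured (camera adjusted p = 0.223, fry 0.00153 higher). Vegfd, a lymphangiogenic growth factor, was at 0 CPM alone and 0.955 ± 0.230 CPM in coculture, at least 15.5-fold higher (adjusted p = 7.96e-06), and Esr1, the oestrogen receptor, was at 0.845 ± 0.699 and 0.793 ± 0.286 CPM (adjusted p = 0.980). Over all genes, 688 had no count alone and at least 10 counts in coculture, against 8 with the reverse. The 688 genes took 0.294% ± 0.0172 of the counts of cocultured libraries, and this share stands beside every gene group described for these libraries. It leaves out genes with any count alone, among them Axl, Csf1 and Tgm2. The share therefore does not measure all RNA that other cells may have added.

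Genes of both polarization programmes rose. Of 13 measured alternative activation genes 7 rose and 2 fell. Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) rose from 1.26 ± 0.578 to 3.23 ± 0.873 CPM, 2.52-fold (log2 1.33, SE 0.316, adjusted p = 0.00151). It rested on 10, 21 and 32 counts alone and 35, 48 and 71 in coculture. Tgm2, a transglutaminase induced by interleukin 4, rose 8.76-fold to 44.7 ± 1.67 CPM, Il4ra, the interleukin 4 receptor chain, rose 3.21-fold to 10.5 ± 0.548 CPM, and the lectin gene Mgl2 rose 9.10-fold to 1.58 ± 0.398 CPM. RNA of TTJ cells was not excluded as a source of the Tgm2 transcripts. The members that fell were Klf4, 1.49-fold to 15.8 ± 1.27 CPM, and Egr2, 1.64-fold to 5.22 ± 0.849 CPM. Clec10a, Clec7a, Pparg and Irf4 did not pass the threshold. Arg1, the arginase of alternatively activated mouse macrophages, had 4, 3 and 7 counts alone and 9, 3 and 5 in coculture, too few for the test. Chil3 and Retnla had no count in any library. The list median was 0.22 (camera adjusted p = 0.0240; adjusted p = 0.143 with an estimated correlation). Without a filter on low counts the adjusted p was 0.104, and without members shared with other lists it was 0.0561. Among camera alternatives the adjusted p ranged from 0.00598 to 0.143, and fry, which tests against no change, gave 3.71e-05. In the FPKM fits Mrc1 no longer passed, with a log2 change of 0.33 at a pseudocount of 1 and 1.05 at 0.1.

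Of 11 measured classical activation genes 8 rose and 0 fell. Il1b, the interleukin 1 beta gene, rose from 0.228 ± 0.0476 to 3.03 ± 0.424 CPM (12.9-fold), Cxcl10, an interferon-induced chemokine, from 8.29 ± 0.867 to 24.3 ± 2.36 CPM (2.94-fold) and Ptgs2, which encodes cyclooxygenase 2, from 46.8 ± 5.64 to 114 ± 4.31 CPM (2.43-fold). Tnf rose from 144 ± 6.21 to 179.9 ± 1.55 CPM (1.25-fold). Nos2, the inducible nitric oxide synthase, was at 37.7 ± 3.82 and 36.3 ± 3.60 CPM (log2 -0.05, SE 0.0845, adjusted p = 0.664), and its sign turned without coculture replicate B, to 0.0073. Il12a and Il12b had no count in any library. The list median was 0.80 (camera adjusted p = 0.00288; adjusted p = 0.0959 with an estimated correlation, the highest among camera alternatives, with 0.000621 the lowest; fry gave 3.72e-05). Restricted to genes with at least 1 CPM alone, the alternative list had 6 rises and 2 falls among 11 members and the classical list 6 rises and 0 falls among 9. Whether the lists differed from each other was not tested.

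**Figure D2:**
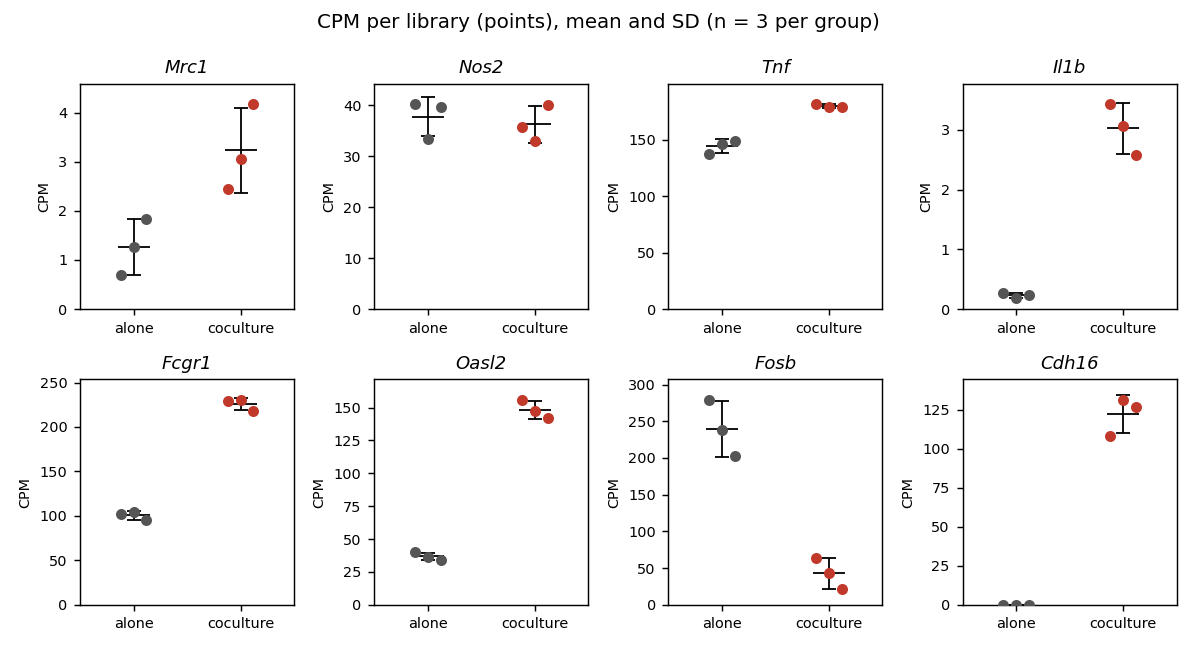
CPM of 8 named genes in each library (points), with the mean and SD of 3 libraries per group (bars), on linear axes from 0. Mrc1, Il1b, Fcgr1 and Oasl2 sit higher in every cocultured library, Tnf by a smaller margin, Nos2 overlaps between the groups, Fosb is lower in coculture, and Cdh16 is at 0 in all 3 lone libraries.

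Interferon response genes rose together, with 22 of 24 higher and 0 lower. Mx1, an antiviral GTPase, rose from 2.31 ± 0.329 to 12.6 ± 1.39 CPM (5.46-fold), the nucleic acid sensor Zbp1 from 11.9 ± 1.25 to 58.9 ± 3.86 CPM (4.94-fold) and Oasl2, of the oligoadenylate synthetase family, from 36.8 ± 2.92 to 148 ± 7.10 CPM (4.03-fold). The median log2 change was 0.60, and all 24 members had at least 1 CPM in lone cells (camera adjusted p = 4.48e-10; adjusted p = 0.0959 with an estimated correlation). All 12 measured antigen presentation genes rose. H2-K1, a class I heavy chain, rose from 98.9 ± 6.32 to 339.8 ± 16.3 CPM (3.44-fold), H2-DMa, a class II chaperone chain, from 5.58 ± 1.15 to 10.3 ± 1.56 CPM (1.85-fold), and its partner H2-DMb1 from 0 to 1.35 ± 0.371 CPM (at least 22.1-fold higher). Class I genes share sequence, so reads of H2-K1 are uncertain. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 were too low to test, with 4, 11 and 9 counts over the cocultured libraries. The list median was 0.64 (camera adjusted p = 1.15e-06; adjusted p = 0.0959 with an estimated correlation), and 11 of its members had at least 1 CPM alone, all of which rose.

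Among 18 measured chemokines and receptors 15 rose and 2 fell. Cxcl1 and Cxcl3, neutrophil chemoattractants, went from 0 counts to 10.2 ± 2.05 CPM (at least 164-fold higher) and 6.14 ± 0.939 CPM (at least 99.3-fold higher). Cxcl2, of the same family and far more abundant in lone cells, fell from 85.6 ± 11.9 to 51.7 ± 9.76 CPM (1.67-fold lower). The other member that fell was Cx3cr1 (1.21-fold lower, to 215 ± 1.65 CPM). Csf1, the macrophage growth factor, rose from 1.79 ± 0.112 to 63.0 ± 5.04 CPM (35.0-fold). RNA of TTJ cells was not excluded as a source of the Cxcl1, Cxcl3 and Csf1 transcripts. The list median was 1.37 (camera adjusted p = 1.61e-06; adjusted p = 0.109 with an estimated correlation). Among the 12 members with at least 1 CPM alone, 9 rose and 2 fell, with a median of 0.51. Of 9 immune checkpoint ligands and receptors 7 rose and 1 fell. Havcr2, which encodes TIM-3, rose from 10.1 ± 0.887 to 39.2 ± 0.865 CPM (3.87-fold) and its ligand gene Lgals9 from 135 ± 4.47 to 246 ± 6.44 CPM (1.83-fold). Cd274, which encodes PD-L1, rose from 6.17 ± 1.14 to 8.60 ± 0.398 CPM (1.39-fold, adjusted p = 0.0211), a call lost without alone replicate A (adjusted p = 0.105) or coculture replicate B (adjusted p = 0.0730), in the DESeq2 Wald test (0.0769) and with FPKM + 1 (0.118) or FPKM + 0.1 (0.0976), within a range of 0.00907 to 0.118 over all alternatives. The checkpoint list had a camera adjusted p of 0.0317, which was 0.0705 without coculture replicate C (adjusted p = 0.183 with an estimated correlation).

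Complement and efferocytosis genes rose in 9 of 11 measured cases, and 0 fell. Axl, a receptor for apoptotic cells, rose from 2.25 ± 0.505 to 117 ± 6.42 CPM (52.6-fold). C1qc, a chain of complement C1q, and Mertk, a receptor related to Axl, went from 0 counts to 1.44 ± 0.228 CPM (at least 23.1-fold higher) and 1.13 ± 0.187 CPM (at least 18.3-fold higher). Both passed the filter only through the cocultured libraries, so their direction was fixed. The median was 1.37 (camera adjusted p = 5.07e-06; adjusted p = 0.0599 with an estimated correlation), and 7 of the 9 members with at least 1 CPM alone rose. Of 15 matrix proteases and growth factors 11 rose and 0 fell. Thbs1, the matrix glycoprotein thrombospondin 1, went from 0 to 37.9 ± 5.04 CPM (at least 617-fold higher), Timp1, a protease inhibitor, rose 12.7-fold to 2.21 ± 0.763 CPM, and Hbegf, an EGF receptor ligand, rose 16.2-fold to 7.75 ± 0.776 CPM. The log2 change of Hbegf was 4.02 and became 5.28 without alone replicate C. RNA of TTJ cells was not excluded as a source of the Axl and Thbs1 transcripts. The list median was 0.84 (camera adjusted p = 5.92e-05; adjusted p = 0.0768 with an estimated correlation), and 7 of the 10 members with at least 1 CPM alone rose.

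Camera did not call the list of general macrophage genes (adjusted p = 0.267), whereas fry called it higher (0.000197). Of 16 identity genes 7 rose and 3 fell, with a median of 0.06. The Fc receptor genes Fcgr3 and Fcgr1 rose from 8.59 ± 0.518 to 24.6 ± 2.12 CPM (2.86-fold) and from 101 ± 4.59 to 226 ± 6.80 CPM (2.25-fold), and Itgam, which encodes CD11b, rose from 53.3 ± 8.82 to 99.3 ± 7.84 CPM (1.86-fold). Adgre1, which encodes F4/80, rose from 73.2 ± 1.66 to 86.8 ± 4.27 CPM (1.19-fold). Tsc2 itself, the gene that TTJ cells lack, rose from 90.0 ± 3.01 to 110.9 ± 0.416 CPM (1.23-fold, adjusted p = 1.78e-05). Of 9 osteoclast genes 2 rose and 4 fell (camera adjusted p = 0.252, fry 0.0366 lower), with a median of -0.16 and a mean of 0.12. Acp5, the tartrate-resistant acid phosphatase, rose 2.24-fold to 29.3 ± 2.44 CPM. Ocstamp, a gene of osteoclast cell fusion, rose 3.52-fold to 3.24 ± 0.624 CPM. Atp6v0d2, a proton pump subunit that is also on the lysosome list, fell 1.58-fold to 13.0 ± 1.12 CPM. Among 26 lysosome genes 13 rose and 6 fell (camera adjusted p = 0.366), and the list was called higher by fry (0.000626) and by camera among genes with at least 10 CPM alone (0.0277). The protease gene Ctsk fell 1.53-fold to 5.72 ± 0.269 CPM.

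Immediate early and heat shock genes fell, 9 of 15 lower and 0 higher. Fosb (chromosome 7, 19302696 to 19310051), a subunit of the AP-1 transcription factor, fell from 239.8 ± 38.3 to 42.9 ± 20.9 CPM (5.66-fold lower). Dusp1, a MAP kinase phosphatase, fell from 198 ± 36.1 to 49.6 ± 16.8 CPM (4.02-fold lower) and Fos from 574 ± 47.9 to 246 ± 57.7 CPM (2.33-fold lower). All 15 members had at least 1 CPM alone, and the median was -0.36 (camera adjusted p = 0.00440; adjusted p = 0.434 with an estimated correlation). The other genes with the largest falls were the serotonin receptor gene Htr1b, from 33.5 ± 2.41 to 8.36 ± 1.30 CPM (4.02-fold lower), Cd83, a surface marker of activated antigen-presenting cells, from 18.5 ± 0.237 to 6.19 ± 1.52 CPM (2.96-fold lower), and Fam13c, from 63.9 ± 1.01 to 26.8 ± 2.13 CPM (2.38-fold lower). Cd83 is on the list of NF-kB targets, of which 2 rose and 7 fell among 16. On that list Traf1, a signalling adaptor, fell 1.56-fold to 23.5 ± 3.06 CPM and Ier3 rose 1.59-fold to 150.2 ± 4.95 CPM. The NF-kB list did not pass (camera adjusted p = 0.0561), but it passed as lower under fry (0.0129), with no filter (0.0195) and without alone replicate C (0.0375) or coculture replicate A (0.0461), within a range of 0.0195 to 0.192 over camera alternatives.

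Oxidative phosphorylation genes fell by small amounts, 17 of 23 lower and 0 higher over all genes tested, and 18 lower when adjusted over the list alone. The 76 ribosomal protein genes had a similar median of -0.18, and the mitochondrial share of counts was lower as well (1.39% against 1.65%). The complex I subunit Ndufa4 fell 1.32-fold to 82.6 ± 1.35 CPM, the complex III subunit Uqcrq 1.25-fold to 73.9 ± 6.82 CPM and Ndufa1 1.24-fold to 23.9 ± 1.16 CPM. The median was -0.19 (camera adjusted p = 4.35e-06; adjusted p = 0.0599 with an estimated correlation). Of 17 glycolysis genes 10 rose and 1 fell. The glucose transporter gene Slc2a1 rose 1.41-fold to 259.7 ± 25.9 CPM, Pfkfb3, a regulator of phosphofructokinase, 1.34-fold to 46.9 ± 7.45 CPM and the lactate exporter gene Slc16a3 1.33-fold to 478 ± 43.4 CPM. Pfkfb3 lost its call with FPKM + 1 (adjusted p = 0.0999) and FPKM + 0.1 (0.0799). The glycolysis list had a camera adjusted p of 0.0339 (adjusted p = 0.594 with an estimated correlation), which was 0.0692 without alone replicate B, 0.0624 without alone replicate C and 0.102 without coculture replicate C. Hypoxia genes rose in 9 of 14 cases and 1 fell. Adm, which encodes adrenomedullin, rose 9.63-fold to 12.8 ± 1.67 CPM and the carbonic anhydrase gene Car9 1.71-fold to 7.86 ± 1.55 CPM, the latter with an adjusted p of 0.0549 with FPKM + 1. Egln3, an oxygen sensor, had 3 counts alone and 13.5 ± 0.967 CPM in coculture, a ratio of 219 (74.6 to 1064), and its fitted log2 change of 7.60 was 10.72 without alone replicate C, the library with those counts. The hypoxia list had a camera adjusted p of 0.0226, which was 0.0705 without coculture replicate C (adjusted p = 0.473 with an estimated correlation).

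Of 32 cell cycle genes 3 rose and 10 fell, with a median of -0.07. Kif11, a mitotic kinesin, fell 1.2-fold to 147 ± 4.47 CPM, Top2a, a topoisomerase, fell 1.2-fold to 561 ± 23.2 CPM, and Rrm2, a ribonucleotide reductase subunit, rose 1.32-fold to 309 ± 12.6 CPM. The camera adjusted p was 0.0240 (adjusted p = 0.473 with an estimated correlation), and it was 0.0734 without coculture replicate C, 0.0863 among genes with at least 1 CPM alone, 0.177 among those with at least 10 CPM alone and 0.0645 under fry. Cholesterol synthesis genes included 2 that rose and 8 that fell among 24. Mvd and Nsdhl, enzymes of the pathway, fell 1.46-fold to 44.9 ± 3.55 CPM and 1.29-fold to 44.3 ± 0.997 CPM. The cholesterol median was -0.07 and the mean was 0.45. Camera called the list lower (adjusted p = 0.0455; adjusted p = 0.473 with an estimated correlation), a call lost at 1 CPM in at least 3 libraries (0.0544), at 10 CPM in lone cells (0.0916) and without alone replicate B (0.122), coculture replicate A (0.0581) or coculture replicate C (0.0968), whereas fry called it higher (0.00272). Camera did not call the lists of lipid uptake and efflux (adjusted p = 0.547), ATF4 amino acid response (0.218), unfolded protein response (0.736) and NRF2 targets (0.518), of which fry called the lipid (0.00272) and NRF2 (0.00159) lists higher.

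Of 16 lipid uptake and efflux genes 7 rose and 5 fell, with 8 rises when adjusted over the list alone. The scavenger receptor genes Cd36, Msr1 and Olr1 rose 2.5-fold to 181 ± 8.59 CPM, 1.94-fold to 526 ± 13.6 CPM and 20.3-fold to 1.82 ± 0.369 CPM. Of 20 ATF4 genes 6 rose and 8 fell, with a median of -0.10 and a mean of 0.52, and fry called this list higher (adjusted p = 0.0110). Vldlr, a lipoprotein receptor gene, went from 0 to 20.9 ± 1.94 CPM (at least 341-fold higher), Ddit4, an inhibitor of mTORC1, rose 3.04-fold to 24.1 ± 0.987 CPM, and Pycr1, of proline synthesis, fell 1.58-fold to 4.28 ± 0.798 CPM (adjusted p = 0.00828), a call lost without alone replicate C (0.0624) or coculture replicate C (0.0613) and in the 3 FPKM fits, within a range of 0.00176 to 0.132 over all alternatives. Of 15 unfolded protein response genes 7 rose and 2 fell, or 3 fell when adjusted over the list alone. Pdia4, a folding enzyme, rose 1.25-fold to 411 ± 8.61 CPM, and Herpud1 and Edem1, of endoplasmic reticulum degradation, fell 1.36-fold to 87.3 ± 0.693 CPM and 1.18-fold to 434 ± 6.08 CPM. Of 14 NRF2 targets 7 rose and 3 fell. Hmox1, the haem oxygenase gene, rose 1.47-fold to 191 ± 9.25 CPM, Me1, malic enzyme, rose 1.30-fold to 46.4 ± 3.54 CPM, and G6pdx, of the pentose phosphate pathway, fell 1.15-fold to 336 ± 10.4 CPM. For the other lists the counts adjusted over the list alone equalled those over all genes tested. In all, 16 of 25 lists passed with the preset correlation, 12 higher and 4 lower, and 0 passed with an estimated correlation, where 9 had an unadjusted p under 0.05, while fry called 23.

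**Figure D3:**
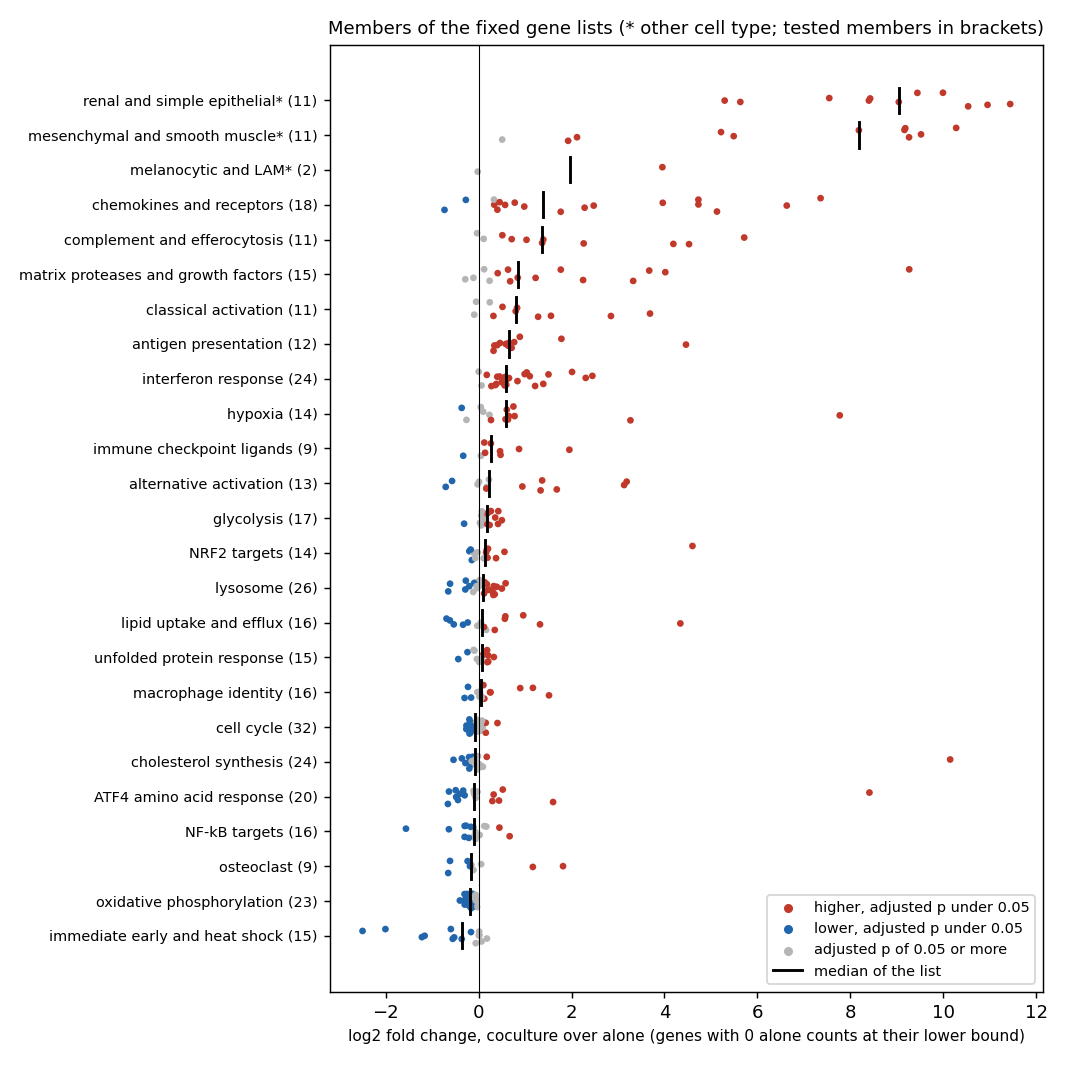
Log2 fold change, coculture over alone, of each tested member of the 25 lists (points), with genes at 0 counts alone drawn at their lower bound, genes with 1 to 3 counts alone at their ratio, and the list median as a black bar. The renal and simple epithelial list has the highest median, 9.05, the interferon response list lies at 0.60 with 0 members called lower, and the immediate early and heat shock list has the lowest, -0.36.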

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

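All alternatives were planned except the limit of at least 10 CPM in lone cells, chosen after seeing the data. The count of 4793 changed genes fell to 3087 with that limit and to 3159 with limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1, where fewer genes were tested. The count of 1270 genes changed at least 2-fold fell to 379 for genes with at least 1 CPM alone, 102 with at least 10 CPM alone, 499 with log2(FPKM + 1) and 353 with that scale and a mean FPKM of at least 1; the first pair tested fewer low genes, and a pseudocount shrinks folds of low genes. With an estimated correlation, 0 of the 16 lists passed, including alternative activation (adjusted p = 0.143) and classical activation (0.0959). The alternative activation list also lost its call with no filter (0.104) and without shared genes (0.0561). Mrc1 lost its call with log2 changes of 0.33 (FPKM + 1) and 1.05 (FPKM + 0.1). The cause was not tested for these lists and Mrc1. Signs reversed for the cholesterol synthesis (0.00272) and ATF4 (0.0110) lists under fry, which does not compare a list with other genes. Below the threshold throughout, the log2 change of Nos2 turned to 0.0073 without coculture replicate B (-0.14 to 0.0073 over libraries left out), and that of Esr1 to 0.0685 with the replicate block, 0.86 without alone replicate A and 0.21 without coculture replicate A (-0.37 to 0.86), 0.20 with limma-voom and 0.0016 with FPKM + 0.1; the cause was not tested.

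Leaving out each library in turn gave 4179 to 4559 changed genes, 1293 to 1391 changed at least 2-fold, 11 to 16 lists, adjusted p of 0.0199 to 0.0417 for the alternative and 0.00132 to 0.00587 for the classical activation list, and log2 changes of 1.06 to 1.71 for Mrc1. The labels do not say whether replicate letters pair the libraries. Deviations of same-letter libraries correlated across genes at 0.0014, 0.0204 and 0.0347, and 4 of 6 libraries correlated best with their own letter. With the replicate block there were 4766 changed genes, 1255 of at least 2-fold, 16 lists and a log2 change of 1.37 for Mrc1, and no list or named gene changed its side of the threshold. The DESeq2 Wald test gave 4223 and 1487 genes and limma-voom 4761 and 1273. Of the other tests of the main results, 58 kept direction and side of the threshold, or lay within 1.5 times of the count. Depth limits Mrc1, Arg1 and genes near 1 CPM.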

Other observations

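In this part the genes of the opening paragraph and Slc5a3 and Slc6a12 were chosen after their values were seen, and so were the tests on genes absent alone and on immediate early genes; the other tests were planned before their results. Genes outside the fixed lists also changed. Siglec1, a sialic acid receptor of interferon-exposed macrophages, rose from 99.2 ± 4.08 to 379.6 ± 18.3 CPM (3.83-fold), Dab2, an endocytic adaptor, from 210.4 ± 8.83 to 577 ± 15.5 CPM (2.74-fold), C5ar1, the C5a receptor gene, from 79.3 ± 3.71 to 175 ± 7.22 CPM (2.21-fold), and Cd300lf, an inhibitory receptor gene, from 9.54 ± 0.483 to 45.3 ± 2.28 CPM (4.75-fold). Clec4n, which encodes Dectin-2, rose from 2.0 ± 0.356 to 16.9 ± 0.749 CPM (8.38-fold), and Itgax, which encodes CD11c, from 2.5 ± 0.524 to 14.3 ± 1.57 CPM (5.73-fold). Itga4, an integrin chain, fell from 2259.9 ± 85.5 to 1347 ± 61.1 CPM (1.68-fold lower), and Klf2, a transcription factor gene, from 40.2 ± 6.48 to 18.2 ± 1.48 CPM (2.21-fold lower). All these passed edgeR's quasi-likelihood test (adjusted p of 1.20e-09 for Klf2, the highest of them).

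The first pattern weighed is the group of genes with no count in lone RAW264.7 cells. RNA of TTJ cells in the sorted fraction is a candidate source, since such RNA would only add transcripts. Genes with at least 10 counts in coculture and none alone numbered 688, and the reverse side held 1.16% as many (8 genes), an imbalance that induction in RAW264.7 cells would give as well. The most abundant markers of the renal and simple epithelial list were Cdh16 (122 CPM), Krt8 (91.8 CPM) and Krt7 (57.2 CPM), and the sort was meant to remove the cells that would carry them. Added RNA and induction of these genes by coculture cannot be told apart, because no library of TTJ cells was used here. The same holds for members of other lists that were low or absent in lone cells and far higher in coculture. Csf1, Axl, Tgm2, Thbs1, Cxcl1 and Vldlr are among them.

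The second pattern is the fall of immediate early genes. Dilution of macrophage RNA by RNA of other cells would lower all genes made only by RAW264.7 cells alike, but 15 of 16 macrophage identity genes lay above the median of the immediate early and heat shock list (-0.36) by more than 2 SE, which argues against dilution as the whole cause and leaves a part of it open. Different handling of the groups before lysis may also have set these genes. The 3 of them with the largest falls declined from replicate A to B to C within both groups, Fosb with 279, 238 and 203 CPM alone and 63.5, 43.3 and 21.7 CPM in coculture, Dusp1 with 226, 211 and 157 and with 63.8, 54.0 and 31.0, and Fos with 616, 586 and 522 and with 293, 264.6 and 182. The 10 genes that cell dissociation is known to raise had a median log2 change of -0.36, but handling and group cannot be told apart, because each group was sorted from its own kind of culture. A response of macrophages to TTJ cells stays open as well, untested.

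The third pattern is the rise of interferon response genes. RNA of TTJ cells might carry such transcripts. The CPM added over the list was 46.0% of the CPM of all genes with no count alone (1351 of 2938 CPM), between the bounds set before the test, so added RNA and a response of RAW264.7 cells cannot be told apart without a TTJ profile.

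Slc5a3 and Slc6a12, transporters of osmolytes, fell 2.24-fold to 114 ± 5.45 CPM and 1.72-fold to 253 ± 12.1 CPM, and the reads of Slc5a3 are uncertain because Mrps6, which fell from 95.1 to 55.1 CPM (log2 -0.79), overlaps it on the same strand. The hypothesis that cocultured cells responded less to tonicity was tested on 6 other tonicity genes, which had a median log2 change of -0.18 and a camera p of 0.179, with members in both directions. The test could not decide it.

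Of 76 ribosomal protein genes tested 5 rose at least 2-fold (Rpl29, Rps2, Rpl21, Rpl26 and Rps18), chosen after their values were seen, while the median of the 76 was -0.18, and reads of these genes are uncertain because of their pseudogenes.

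The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For each of 5 results 1 of the 10 splits, the real one, gave a result as large. In edgeR's quasi-likelihood test the real split gave 4793 changed genes against 0 for the highest of the others (115 to 216 genes at an unadjusted p under 0.05, against 5792; no other tool was run on the splits), 1270 against 0 for changes of at least 2-fold, and 16 lists against 12. The smallest camera p of the other splits was 0.0177 for alternative activation (real 0.0123) and 0.00791 for classical activation (real 0.00104). Each other split sets 2 lone and 1 cocultured library against 1 lone and 2 cocultured ones, so part of the difference between the groups remains in it. The rest of that difference widens the spread within each side and so lowers the number of genes called. The 0 genes of the other splits therefore say little about chance.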
